A study of Homo sapiens with 33 samples.

How the data were processed

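HA-tagged MITF was profiled by CUT&Tag in 33 libraries of UACC-257 melanoma cells, and each library was deposited as a list of peaks in narrowPeak form, with coordinates on hg38, per the labels. The submitters' processing notes name bcl2fastq 2.20.0.422, Bowtie2 2.3.4.3 and MACS2, whose version is not given in the sources used here. Whether a control library or duplicate removal was used in calling is not given in the sources used here either. Peaks were called per library, not on pooled libraries, per the labels. Each peak carries, as the authors deposited it, a fold enrichment (a ratio of the summit over the local background), the −log10 p and −log10 q of the summit, the offset of the summit, and a score that is 10 times the −log10 p held to a whole number and was not used. The lowest −log10 p of a list was 2.00 to 2.18, so the lists reach down to a p-value near 0.01. Of the G244E lists, 2 held exactly 300000 peaks, which points to a limit on their length. The deposited values are the authors' own. They were used to describe, rank or filter peaks within a list, to count peaks past a threshold, and to recover relative depth as described below.

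The lists of replicates 2 and 3 of rep217A were identical, as were those of rep263A, and each such pair was counted as 1 library. Peaks on chromosomes 1 to 22 and X were kept, and the other sequences held 0.0833% to 0.207% of each list. The annotation was the RefSeq gene table of the same build, which gives the span of each gene without its strand or exons. The distance to a transcription start that was planned was therefore replaced by the distance to either end of a gene. All 144 genes of the 10 fixed lists were found in it. The planned counts of E-boxes and of 16 motifs at summits, and of peaks on MITF exons, need genome sequence or exons and were not analysed here.

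No total count of reads was used here, so relative depth was recovered from the deposited values. MACS2 gives the fold as the summit pileup plus 1 over the background plus 1, and the p-value as the Poisson tail above the pileup, which together fix both. A whole-number pileup met the deposited values within their rounding for 100% of peaks with −log10 p below 12 in every library, against 1.83% to 36.6% when fold and p were shuffled. The commonest background of a library was taken as its relative depth. It was the same 0.03 in all Empty libraries whatever their length, and was taken as an upper limit there. Libraries were thinned by binomial sampling of the recovered pileups, and the p of each summit was computed again. The target was the depth of the shallowest library other than Empty (0.108, called the common depth) or the limit of Empty (0.03). Thinned values per library are means of 5 draws, and counts of group-specific regions rest on 1 draw. Only summits already called can be thinned, so a thinned list lacks summits that a shallow library would have called by chance. Thinned peaks also keep the width called at full depth, so those of a deep library can overlap regions more easily than those of a shallow one. Depth limits what the shallow libraries can show, and a region not called in K243A, G244E, rep217A or Empty at its own depth may have been undetectable there and need not be absent.

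Strongest peaks were the 10000 of highest −log10 q in each library. Regions were compared by overlaps of at least 1 bp. WT regions were overlaps between the peaks of a pair of WT libraries. A WT library was scored on the pair without itself, and any other library on the mean of the 3 pairs. Group-specific regions were merged intervals called in all libraries of a group and none of the other. A list gene counted as strong when the summit of a strongest peak lay within 5000 bp of a gene end. Named regions and genes followed a fixed rule, namely the 10 WT-specific regions of highest mean WT rank, the 3 lost and 3 gained regions of highest mean rank for each variant, the 12 genes of highest mean WT rank over the pigmentation, survival, lysosome and lineage lists, and every pigmentation gene absent from the strongest WT peaks. Regions were named by the nearest end of a protein-coding gene. Some of the regions this rule takes are not reported here.

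The groups, measures, tests, gene lists, naming rule and the other settings tried, except where said, were fixed before the data were examined. The depth recovery, both thinnings, the −log10 p of at least 8 and the change to gene ends came after. Each measure was tested over all 31 distinct libraries with a permutation of group labels (100000 resamples, seed 1). The highest absolute standardised difference over a family of 19 comparisons (each group against WT and against Empty) gave two-sided adjusted p-values with a threshold of 0.05, and 1e-05 is the smallest they can give. At the common depth the Empty libraries were left out, and the family held only the 9 comparisons of a variant with WT. At the depth limit of Empty all 19 were kept, with the Empty libraries in the pooled spread. P-values at these depths therefore come from different tests. An F permutation test covered any difference among the groups. Exact tests of a variant against WT cannot go below 0.1 with 3 libraries against 3, or 0.2 with 3 against 2, and so were not used for calls. Alternatives were a −log10 q of at least 5, ranking by fold, the 5000 or 20000 strongest peaks, only the strongest summit of each interval, overlaps of at least 50%, gene bodies with 10000 bp to each side, leaving out each replicate in turn, a replicate block, and identical lists counted separately.

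The steps were tested on simulated data. Overlaps equalled a base-by-base count in 100% of 200 trials, and the pileup was recovered at 99.98% of 5030 simulated summits. With equal binding at 30000 simulated sites, 8153 peaks passed a −log10 p of 8 in a deep library and 1323 in a shallow one, and 1350 in the deep one after thinning. Over 300 simulations without differences, the adjusted test made any call in 5.33% and the F test in 5%, and a shift of K243A by 6 SD was called in 100%. The simulated groups had equal spread. Unequal spreads, and false calls of an unchanged variant beside groups that differ, were not simulated. All of 500 planted group-specific regions were found. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.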

Results

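MITF, the master transcription factor of the melanocyte lineage, was profiled on chromatin in UACC-257, an established human melanoma cell line. The labels describe cells with MITF knockdown treated with doxycycline, and HA-tagged protein was followed by CUT&Tag, in which an antibody, here anti-HA, directs a transposase to cut and tag the DNA around its target. The series held 33 libraries in 11 groups of 3: wild-type MITF (WT), an empty control (Empty) and 9 MITF variants named as in the sample titles (A264C, E260A, G244E, K243A, N278D, Q261A, Y253A, rep217A and rep263A). In rep217A and in rep263A, the lists of replicates 2 and 3 were identical and were counted as 1 library, which left 31 distinct libraries and n = 2 in these groups. The labels do not say whether replicates were separate cultures, so all p-values below measure only the spread between these samples.

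Each library came as a list of peaks called on that library alone, with 81488 to 300000 peaks covering 18.2 to 71.2 Mb. Depth differed between groups. The background pileup, a measure of relative depth recovered from the lists, averaged 1.15 ± 0.0638 in WT (SD, n = 3), 1.27 ± 0.226 in A264C, 1.06 ± 0.0882 in Y253A, 0.997 ± 0.118 in N278D, 0.895 ± 0.0631 in E260A and 0.774 ± 0.0983 in Q261A. It was 0.457 ± 0.0427 in rep263A and 0.312 ± 0.0508 in rep217A (n = 2 each), 0.178 ± 0.0589 in K243A and 0.129 ± 0.0214 in G244E (n = 3 each), and at most 0.03 in every Empty library. WT was thus 8.94 times as deep as G244E, 6.48 times as deep as K243A and at least 38.5 times as deep as Empty. Values at a common depth, obtained by thinning, are therefore given beside own-depth values for strong peak number, recovery among the strongest peaks, gene-end share and group-specific regions. For gene lists they are given where a call changed. Recovery over all listed peaks, library similarity and the counts at the MITF gene are at own depth only.

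The comparison of WT with Empty asked which regions carried HA-MITF signal above the control. WT libraries shared 39721 regions that no Empty library had, against 169 regions in every Empty library and no WT library. Such clean splits made up 81.9% of the regions called in exactly 3 of the 6 libraries, where chance gives 10%. The 10% takes the 6 libraries as exchangeable. WT was at least 38.5 times as deep as Empty, which alone can raise the share of such WT regions. Among the 10 of these regions ranked highest in the WT lists were regions near or inside HTR2A, EXT1, MERTK, TTYH3, CDCA4, DUSP22, MAGI1 and MINAR1. The highest was inside HTR2A, a serotonin receptor gene (chromosome 13, 46866073 to 46866702, hg38). Others lay inside EXT1, which encodes a heparan sulfate polymerase (chromosome 8, 117847542 to 117848426), and inside MERTK, which encodes a receptor tyrosine kinase (chromosome 2, 111962891 to 111963784). These named regions were called in every library of all 9 variants. With every library thinned to the depth limit of Empty and peaks held to a −log10 p of at least 8, 547 regions were specific to WT and 42 to Empty. That limit is an upper bound for Empty, so thinned WT may still be deeper than Empty and depth may still contribute.

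WT and Empty also differed in the number of strong peaks. At a −log10 q of at least 5, WT had 94923 ± 2469 peaks and Empty 881 ± 386 (SD, n = 3 each), a log2 difference of 6.84 (max-statistic permutation test over 19 comparisons, two-sided, adjusted p = 1e-05, the smallest the permutations can give). At the depth limit of Empty the log2 difference was 1.16, with 4057 ± 182 and 1858 ± 535 peaks of −log10 p of at least 8 (n = 3 each, permutation p = 0.00065). Empty may lie below that limit, so this difference may still hold a part due to depth. Without a stricter threshold, WT listed 207353 ± 17591 peaks and Empty 113858 ± 28175, a 1.86-fold difference that did not pass the test (n = 3 each, permutation p = 0.178). The exact test of 3 libraries against 3 cannot go below 0.1. Of the Empty peaks, 64.1% ± 3.46 rested on a pileup of 1 tag (n = 3), as did 0% in WT. So did 52.8% and 58.8% in G244E replicates 1 and 2 and 54.7% in K243A replicate 1, against 0% in the other libraries of these groups. A pileup of 1 can pass the threshold only over a low background. That background was 0.108 to 0.132 in these libraries, and 0.151 to 0.244 in the others of G244E and K243A. The split thus follows from depth and threshold. The share of WT regions overlapped by all listed peaks was 55.0% and 52.4% in G244E replicates 1 and 2 against 47.0% in replicate 3, and 58.9% in K243A replicate 1 against 50.5% and 57.1%.

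In WT, the strongest peaks lay at more genes of pigmentation and of lysosomes than in Empty. The word strong marks the rank within a library only. The weakest of the 10000 strongest peaks had a −log10 q of 92.1 to 100 in WT and 1.63 to 1.87 in Empty. Every one of the 16 pigmentation genes had a WT region within 5000 bp of a gene end. So had all 16 housekeeping genes, 10 of 12 lymphoid, 8 of 12 hepatocyte and 8 of 12 keratinocyte markers. Such a region alone therefore does not set pigmentation genes apart. Of the pigmentation genes, 11 had a peak among the 10000 strongest of all 3 WT libraries: TYR, PMEL, SLC45A2, SLC24A5, TRPM1, OCA2, MLPH, MYO5A, RAB38, MC1R and GPNMB. TYR encodes tyrosinase, the rate-limiting enzyme of melanin synthesis, and PMEL the fibril protein of melanosomes. TYRP1, DCT, MLANA, GPR143 and RAB27A were absent from the strongest peaks of all WT libraries. The count of strong pigmentation genes was 11 ± 0 in WT and 4.33 ± 2.31 in Empty (SD, n = 3 each, permutation p = 0.00011). For 22 lysosome and autophagy genes it was 17.7 ± 0.577 and 7 ± 1 (n = 3 each, permutation p = 1e-05). For comparison, 10000 random gene lists of the same size were drawn from protein-coding genes with a strong peak in any library. The fixed lists were not held to such genes, which can lower their percentiles. Among the random lists, the WT counts stood at the percentiles 97.2 for pigmentation and 99.98 for lysosome. Empty stood at 0.67 and 1.3. Housekeeping genes stood high in both, at 99.86 in WT and 99.99 in Empty. Ranked by fold enrichment, in place of −log10 q, the WT excess over Empty became -0.667 pigmentation genes and 1.33 lysosome genes, neither of which passed the test.

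Among the 10000 strongest peaks by −log10 q, the other lists did not pass the test between WT and Empty, except that lineage regulators were fewer in WT. For 16 survival, cell cycle and metabolism genes, all with a WT region, the strong count was 7.67 ± 0.577 in WT and 7 ± 1.73 in Empty (n = 3 each, permutation p = 0.985), but the WT minus Empty difference passed the test at 3.67 over gene bodies, 1.67 with the 5000 strongest peaks and 3.27 at the depth limit of Empty, and in the other direction, at -3.33, with ranking by fold. Of 13 melanocyte lineage regulators, WT had 2 ± 0 and Empty 6 ± 1 (n = 3 each, permutation p = 2e-05). IRF4, which encodes a transcription factor, was strong in 3 of 3 WT libraries and 0 of 3 Empty libraries, while SOX10, which encodes a neural crest transcription factor, was strong in 0 WT and 3 Empty libraries. These genes were picked after their values were seen. Most of the peaks that count as strong in Empty had a −log10 q below 5, so strong in Empty does not mean what it means in WT. The lineage difference did not pass the test at the depth limit of Empty (-2.60, permutation p = 0.0566) or with the 20000 strongest peaks (-2). Housekeeping genes, a list of promoters open in any cell, had 13 ± 0 of 16 strong genes in WT and 12.7 ± 0.577 in Empty (n = 3 each, permutation p = 1), a difference that ranking by fold turned to -7.67. DNA repair genes had 6.33 ± 0.577 of 10 in WT and 5.33 ± 2.08 in Empty (n = 3 each, permutation p = 0.878), a difference that passed at 3.33 with the 20000 strongest peaks. Invasive-state genes had 4.33 ± 1.15 and 4.33 ± 0.577 of 15, and fewer in WT with ranking by fold (-3.33) and with the 5000 strongest peaks (-2.33). Hepatocyte, lymphoid and keratinocyte markers, lists of 12 genes each, had 0.667 ± 1.15, 1.33 ± 0.577 and 1 ± 0 strong genes in WT, and 1.33 ± 1.53, 2.33 ± 0.577 and 0.667 ± 0.577 in Empty (n = 3 each). Lymphoid markers were fewer in WT over gene bodies (-3).

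The 12 list genes with the highest mean WT rank were RRAGC (mean rank 37), APEX1 (39.3), WIPI1 (82.3), NEU1 (114), ATP6V0D1 (481), ATP6V1B2 (543), ACP5 (736), CDK2 (757), GPNMB (883), ATP6V1C1 (1066), UVRAG (1108) and HIF1A (1207). RRAGC encodes a Rag GTPase of lysosomal nutrient sensing. Its WT peak covered chromosome 1, 38859246 to 38860440, across an end of the gene (38838198 to 38859772), with a deposited fold of 21.7 in WT replicate 1. WIPI1, an autophagy gene, had its peak at chromosome 17, 68456687 to 68458210, across a gene end (68457496). ACP5, which encodes an acid phosphatase, had its peak inside the gene at chromosome 19, 11577195 to 11578649. The peak counted for APEX1 (chromosome 14, 20461086 to 20462067) lay outside the gene, which ends at 20457767. So did that of CDK2 (chromosome 12, 55973451 to 55974135), which ends at 55972789. These peaks may belong to neighbouring genes. All 12 genes were called in every library of every group, Empty included. Among the strongest peaks, ACP5 and ATP6V1C1 were absent from all 3 Empty libraries, RRAGC, ATP6V1B2 and GPNMB were present in 1 of 3, and APEX1, WIPI1, NEU1, ATP6V0D1 and CDK2 in 3 of 3.

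The comparisons of the variants with WT asked how much of the wild-type binding each variant kept. WT regions, those shared by a pair of WT libraries among their 10000 strongest peaks, numbered 7410 to 7639. A WT library found 94.4% ± 1.65 of the regions of the other pair (SD, n = 3). A264C found 94.7% ± 0.148 (n = 3), 0.289 percentage points above WT (permutation p = 1). All other variants found fewer. The values were 86.6% ± 0.0937 in rep263A (n = 2, permutation p = 0.00433), 85.0% ± 2.21 in Q261A (n = 3, permutation p = 0.00061), 81.7% ± 0.692 in N278D (n = 3, permutation p = 4e-05) and 81.6% ± 0.241 in Y253A (n = 3, permutation p = 3e-05). They were 80.1% ± 0.171 in E260A, 76.3% ± 0.295 in K243A and 66.3% ± 1.197 in G244E (n = 3 each), and 63.3% ± 0.0456 in rep217A (n = 2), each with a permutation p of 1e-05. Empty found 39.3% ± 4.55 (n = 3, permutation p = 1e-05). Without replicate 2 of every group, the Q261A difference did not pass the test (-9.15 percentage points, permutation p = 0.0826). Without replicate 1 or without replicate 2, 1 library of rep263A was left, assumed to vary like the other groups, and its difference hardly moved (-7.46 and -7.24, permutation p = 0.0654 and 0.315).

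**Figure D1:**
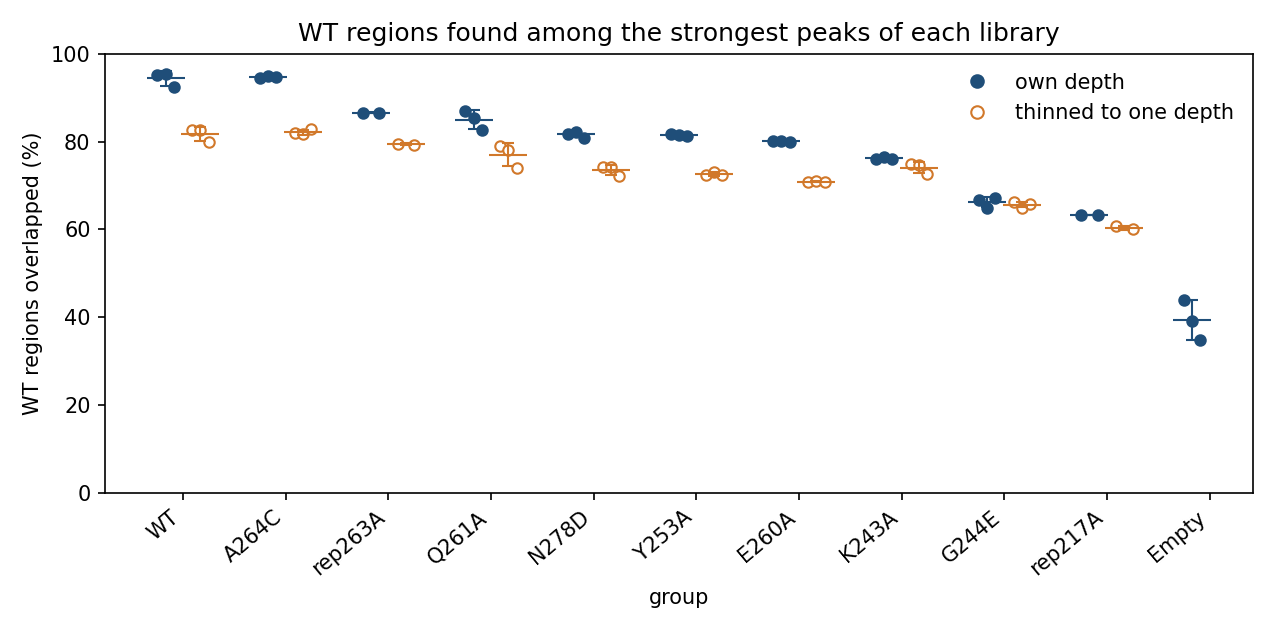
Percent of WT regions overlapped by the 10000 strongest peaks of each library (y axis, %) in each group (x axis), at its own depth (filled points) and thinned to a common depth (open points, not drawn for Empty). Points are libraries, and lines give the mean and SD. At their own depth, WT and A264C averaged 94.4% and 94.7%, and rep217A, at 63.3%, was the lowest of the variants.

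At the common depth, WT libraries found 81.8% ± 1.60 and A264C 82.2% ± 0.549 (n = 3 each). Q261A (77.1% ± 2.64), K243A (74.1% ± 1.27), N278D (73.6% ± 1.18), Y253A (72.7% ± 0.434), E260A (70.9% ± 0.108) and G244E (65.6% ± 0.628) remained below WT (n = 3 each), with a permutation p of 0.00147 for Q261A and 1e-05 for the others. So did rep217A, at 60.4% ± 0.459 (n = 2, permutation p = 1e-05). The rep263A difference was -2.28 percentage points, with 79.5% ± 0.144 found (n = 2, permutation p = 0.278). At the depth limit of Empty, K243A (-3.02 percentage points, permutation p = 0.38), Q261A (-3.03, permutation p = 0.379) and rep263A (-1.53) did not pass the test. Over all listed peaks, E260A (79.97% ± 0.582), N278D (82.2% ± 1.32), Q261A (78.2% ± 1.07) and Y253A (81.7% ± 1.32) did not differ from WT (83.7% ± 2.70) by the permutation test (n = 3 each). K243A (55.5% ± 4.43) and G244E (51.5% ± 4.10) did (n = 3 each, permutation p = 1e-05), as did rep217A (57.2% ± 1.96, n = 2, permutation p = 1e-05) and rep263A (75.0% ± 2.06, n = 2, permutation p = 0.0268). With 1 library of rep263A left, without replicate 1 or without replicate 2, its difference over all peaks stayed at -8.65 and -8.33 percentage points and did not pass (permutation p = 0.185 and 0.276).

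At the authors' threshold the F permutation test found no difference in peak number among the 11 groups (permutation p = 0.408). G244E and K243A mixed lists with and without peaks of 1 tag, and their SD was 0.915 and 0.803 on the log2 scale. The number of strong peaks fell in K243A, G244E and rep217A. At a −log10 q of at least 5, K243A had 33276 ± 6050 and G244E 25322 ± 3955 peaks (n = 3 each), log2 differences from WT of -1.53 (permutation p = 0.00195) and -1.92 (permutation p = 0.0012). The rep217A libraries had 39629 ± 2437 (n = 2), a log2 difference of -1.26 (permutation p = 0.00407). Thinned to the common depth, with a −log10 p of at least 8, WT had 18849 ± 416 peaks, K243A 21122 ± 2156 and G244E 20964 ± 717 (n = 3 each), differences of 0.16 and 0.15 on the log2 scale that did not pass the test (permutation p = 0.175 and 0.204). The rep217A count stayed lower, at 15311 ± 1130 (n = 2), a log2 difference of -0.30 (permutation p = 0.00839). There, N278D (26718 ± 1451), Q261A (25888 ± 2073), Y253A (24848 ± 1149) and E260A (23232 ± 661, n = 3 each) had more peaks than WT, with log2 differences of 0.50, 0.45, 0.40 and 0.30 (permutation p = 3e-05, 5e-05, 0.00022 and 0.00349). So had rep263A (24848 ± 243.6, n = 2), by 0.40 (permutation p = 0.00064). A264C had 20919 ± 930 (n = 3), a log2 difference of 0.15 (permutation p = 0.222). At the depth limit of Empty, Q261A passed (0.57, permutation p = 0.0419), while N278D (0.51), rep263A (0.53), Y253A (0.36), E260A (0.15) and rep217A (-0.28) did not (permutation p = 0.0709, 0.106, 0.313, 0.989 and 0.745). That test also held the Empty libraries, unlike the test at the common depth.

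Pigmentation genes left the strongest peaks in G244E. Its strong count was 6 ± 2 of 16 (n = 3, permutation p = 0.00135 against WT), and TYR, TRPM1 and SLC24A5 were strong in 0 of 3 G244E libraries. K243A had 9.67 ± 0.577 (n = 3, permutation p = 0.654) and rep217A 9 ± 0 (n = 2, permutation p = 0.321), where TRPM1 and SLC24A5 were strong in 0 of 2 libraries. The other variants had 11.7 to 12 strong pigmentation genes. MLANA, which encodes a melanosomal antigen and was strong in no WT library, was strong in 3 of 3 libraries of E260A, N278D, Q261A and Y253A and in 2 of 2 of rep263A. It was also strong in 2 of 3 A264C libraries and in 1 library each of K243A, rep217A and Empty, and its mean WT rank of 11297 lay just past the 10000 strongest. IRF4 was strong in no G244E or K243A library. BIRC7, which encodes an inhibitor of apoptosis and was strong in all WT libraries, was strong in no G244E or rep217A library. SOX10, strong in no WT library, was strong in 3 of 3 K243A and 2 of 2 rep217A libraries. These single genes were picked after their values were seen, and all of them were called in the complete lists of these libraries. The G244E pigmentation difference was -1.67 with the 20000 strongest peaks, -2.67 over gene bodies and 0 with ranking by fold, none of which passed the test, and ranking by fold turned K243A to 3.33 genes above WT.

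Lysosome and autophagy genes passed the test as fewer than in WT in 6 variants, 3 of which did not pass with a replicate block. Against 17.7 ± 0.577 of 22 in WT, the strong count was 13.3 ± 1.15 in G244E (n = 3, permutation p = 0.00215), 14 ± 0 in rep263A (n = 2, permutation p = 0.00932) and 14.5 ± 0.707 in rep217A (n = 2, permutation p = 0.0228). E260A (15 ± 1.73), K243A (15 ± 0) and N278D (15 ± 1) each passed with a permutation p of 0.032 (n = 3 each), and with a replicate block, although replicate numbers did not pair the libraries, each had a permutation p of 0.0556. Q261A (15.3 ± 0.577, permutation p = 0.064) and Y253A (15.7 ± 0.577, permutation p = 0.123) did not (n = 3 each), and A264C had 18 ± 0 (n = 3). The median of random lists of 22 genes, 9.67 in WT, was also lower in N278D (8.33), E260A, rep217A and rep263A (9 each) and higher in K243A (11) and G244E (11.7). Against these lists the counts stood at the percentiles 99.92 in N278D, 99.64 in E260A, 99.3 in rep217A, 98.57 in rep263A, 97.09 in K243A and 78.78 in G244E. CTSA, which encodes the lysosomal protective protein cathepsin A, was strong in 3 of 3 WT and A264C libraries and in none of E260A, K243A, N278D, Q261A and Y253A, a gene picked after its values were seen. At the depth limit of Empty, K243A (-1.53), rep217A (-3.07) and rep263A (-2.57) did not pass. None of the 6 passing differences passed with the 20000 strongest peaks (0 to -2.33 genes), and over gene bodies E260A (-2), N278D (-2.33), rep217A (-1.67) and rep263A (-2.17) did not. Ranking by fold turned G244E, K243A and rep217A to 3.67, 5.33 and 5 genes above WT and ended the passing results of E260A (-2.67) and rep263A (-0.5). With the 5000 strongest peaks rep217A did not pass (-3.33), and Q261A (-6) and Y253A (-6.67) did. Leaving out replicate 1, 2 or 3 ended the passing result of E260A (-1.5 to -3.5), K243A (-2.5 to -3) and N278D (-2 to -3), replicate 1 or 2 that of rep217A (-4 and -2.5) and rep263A (-4 and -3.5), with 1 library left in each, and replicate 2 that of G244E (-4.5).

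Among the remaining lists, DNA replication and repair genes fell from 6.33 ± 0.577 of 10 in WT to 3.67 ± 1.15 in E260A and 3.67 ± 0.577 in N278D (n = 3 each, permutation p = 0.0233 each). GTF2H1, which encodes a subunit of the repair and transcription factor TFIIH, and EME1, which encodes an endonuclease subunit, were strong in all WT libraries and in none of these variants' libraries, and were picked after their values were seen. These differences did not pass with the 20000 strongest peaks (-1.67 each), with ranking by fold (-2 and -2.33) or over gene bodies (-2.67 and -3), nor, for N278D, at the depth limit of Empty (-1.67), nor without replicate 1 (-2.5 in E260A and -3 in N278D) and, for N278D, without replicate 2 (-2.5). Lineage regulators were higher in rep217A, at 5 ± 0 against 2 ± 0 of 13 in WT (n = 2 and n = 3, permutation p = 0.00225), but not at the depth limit of Empty (a difference of 0.600), with ranking by fold (1.17), with the 5000 strongest peaks (2) or over gene bodies (2). With 1 library of rep217A left, without replicate 2, the difference stayed at 3 and did not pass (permutation p = 0.157). Keratinocyte markers were higher in E260A, at 2.67 ± 0.577 against 1 ± 0 of 12 (n = 3 each, permutation p = 0.00744), through KRT14 and IVL. The difference did not pass with the 5000 strongest peaks (0), with ranking by fold (0.333), at the depth limit of Empty (0.467), with the 20000 strongest peaks (1), or without replicate 1 or without replicate 3 (1.5 each). No variant passed the test against WT in survival, invasive-state, housekeeping, hepatocyte or lymphoid genes among the 10000 strongest peaks by −log10 q at its own depth. Other settings did give such calls. With the 5000 strongest peaks, housekeeping genes were fewer in E260A and Q261A (-2.33 each) and Y253A (-3), and survival genes in G244E (-1.67). Ranking by fold gave more survival (2.67), invasive-state (2) and housekeeping genes (6) in G244E and in K243A alike. At the common depth, housekeeping genes were fewer than in WT in E260A (-1.4), N278D (-1.8) and Y253A (-1.87), survival genes were more in E260A (1.47) and invasive-state genes in rep217A (2.3). There, DNA repair genes were also fewer in Y253A (-2.13) and rep217A (-1.83), lysosome genes in Q261A (-3.53) and Y253A (-2.27), and lineage genes more in K243A (1.2). The F permutation test of any difference among the 11 groups, Benjamini-Hochberg adjusted over the 10 lists, gave p = 5e-05 for lysosome and for lineage genes, 0.0001 for pigmentation, 0.00605 for DNA repair and 0.0151 for keratinocyte genes. It gave 0.0723 for invasive-state and for housekeeping genes, 0.08 for survival, 0.178 for lymphoid and 0.565 for hepatocyte genes.

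More of the strongest peaks lay at gene ends in G244E and K243A, and fewer in 5 other variants. In WT, 40.3% ± 1.43 of the strongest peaks had their summit within 1000 bp of an end of a protein-coding gene (SD, n = 3). The share was 50.7% ± 1.47 in G244E (n = 3, permutation p = 7e-05) and 47.9% ± 0.848 in K243A (n = 3, permutation p = 0.00275). It was 29.9% ± 1.12 in N278D and 29.9% ± 1.36 in Y253A (n = 3 each, permutation p = 7e-05 each), 32.6% ± 2.54 in Q261A (n = 3, permutation p = 0.00223), 34.1% ± 1.99 in E260A (n = 3, permutation p = 0.0164) and 33.4% ± 0.467 in rep263A (n = 2, permutation p = 0.0167). A264C had 39.1% ± 0.758 (n = 3, permutation p = 0.995) and rep217A 36.5% ± 0.735 (n = 2, permutation p = 0.401). All 7 passing differences of variants still passed at the common depth, at 11.2 percentage points for G244E, 8.31 for K243A, -9.71 for N278D, -9.59 for Y253A, -7.07 for Q261A, -6.32 for rep263A and -6.17 for E260A. Ranking by fold ended the rep263A call (-2.31) and turned rep217A to 5.77 points above WT, and only the strongest summit of each interval ended the calls of E260A (-4.11) and rep263A (-5.18). At the depth limit of Empty, rep217A lay below WT too (-6.15). Empty had 34.2% ± 4.70 (n = 3, permutation p = 0.0195), a difference that turned with ranking by fold, where WT lay -11.5 percentage points from Empty. The Empty share rested mostly on peaks of −log10 q below 5. Without replicate 2, the differences of G244E (9.82), K243A (7.40), Q261A (-7.08), E260A (-7.29), rep263A (-6.68, with 1 library left) and Empty (WT minus Empty 5.58) did not pass, and without replicate 3 those of Q261A (-6.19), E260A (-4.51), rep263A (-6.23) and Empty (3.35).

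**Figure D2:**
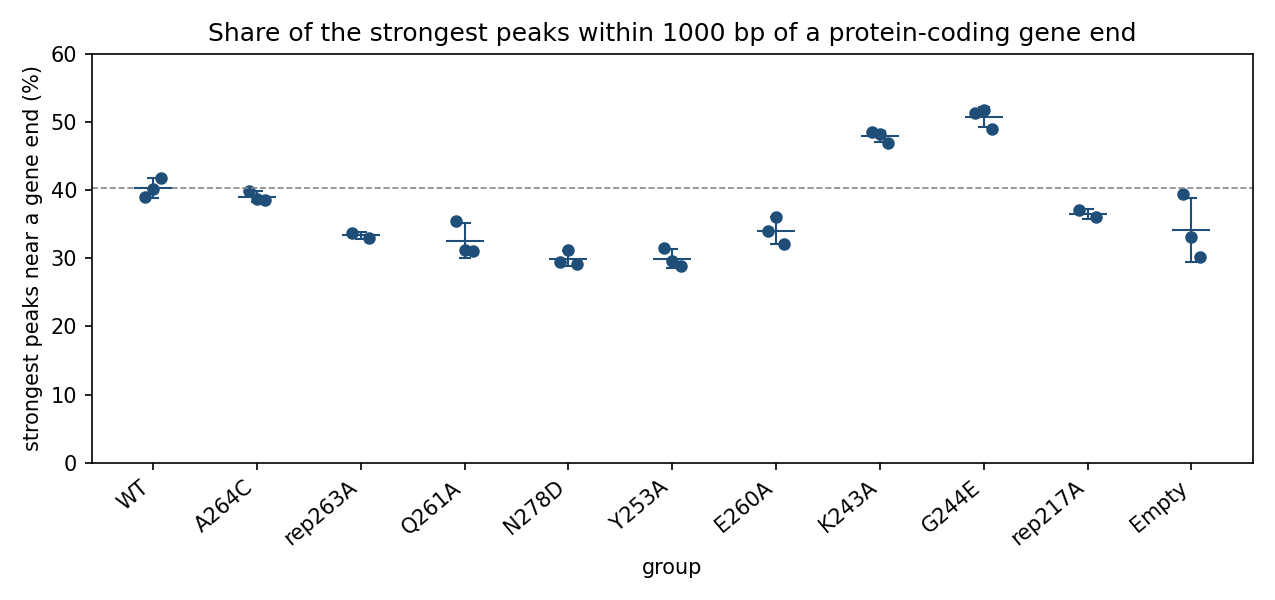
Percent of the 10000 strongest peaks of each library with the summit within 1000 bp of an end of a protein-coding gene (y axis, %) in each group (x axis). Points are libraries, lines give the mean and SD, and the dashed line is the WT mean of 40.3%. G244E and K243A lay above it, at 50.7% and 47.9%, and N278D and Y253A lowest of the variants, at 29.9% each.

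Group-specific regions were counted between each variant and WT. Regions called in every WT library and in no library of the variant numbered 1420 for A264C, 3482 for N278D, 3696 for Y253A, 3874 for E260A, 4015 for Q261A, 6045 for rep263A, 12427 for K243A, 15411 for G244E and 17997 for rep217A. Regions called only in the variant of each pair numbered 1871, 7728, 8252, 10012, 3327, 3879, 206, 498 and 8811 in the same order. With only 1 of their libraries left, the regions of rep217A and rep263A alone rose to 125202 and 75936. Clean splits made up 13.7% of the regions called in exactly 3 of the 6 libraries for A264C and 31.2% to 46.5% for E260A, G244E, K243A, N278D, Q261A and Y253A, where chance gives 10%. The 10% takes the libraries as exchangeable. WT was 6.48 times as deep as K243A and 8.94 times as deep as G244E, which alone can raise their shares. The A264C and rep263A counts, 3291 and 9924 regions in both directions together, lay close to the highest of the other splits of the same libraries, 2567 and 9290. At the common depth and a −log10 p of at least 8, regions of WT alone numbered 2188 against rep217A, 1007 against G244E and 390 against K243A, and 86 to 262 against the other variants. Regions of the variant alone then numbered 1837 in rep263A, 1554 in N278D, 1290 in Y253A, 1235 in Q261A, 1225 in E260A, 1133 in rep217A, 735 in G244E, 416 in K243A and 330 in A264C. A region of rep217A or rep263A needed only 2 libraries, which raises these counts by construction, so they do not compare with those of the variants with n = 3.

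**Figure D3:**
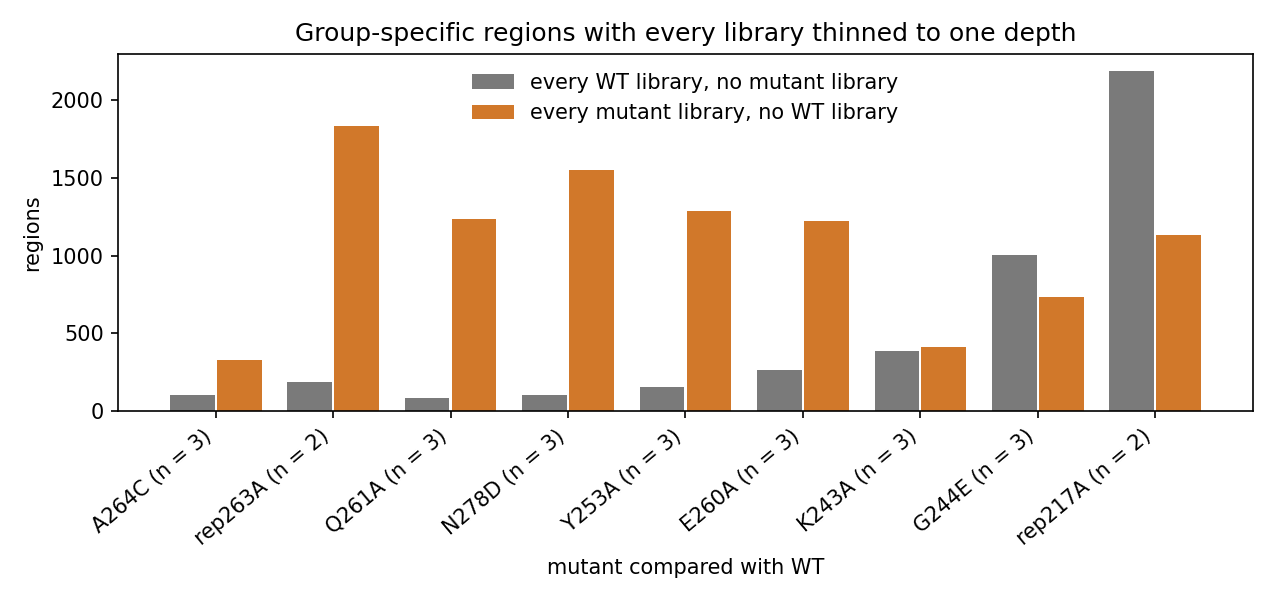
Number of group-specific regions (y axis) for each variant against WT (x axis), with every library thinned to a common depth. Grey bars count regions in every WT library and no variant library, orange bars the reverse. Among variants with n = 3, the WT bar reaches 1007 for G244E and the variant bar 1554 for N278D. Counts of rep217A and rep263A (n = 2) are raised by construction.

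Of the lost regions ranked highest in WT, those of G244E and rep217A were strong WT peaks. G244E had no peak in any library at a region near IGSF3 (chromosome 1, 116682582 to 116683118), near CST2 (chromosome 20, 23841862 to 23842806) or inside FADD, which encodes a death receptor adaptor (chromosome 11, 70204903 to 70205656), each among the strongest peaks of all 3 WT libraries. In rep217A the lost regions lay inside FAR2 (chromosome 12, 29154874 to 29155580) and near SPATS2L and GPCPD1, also strong in 3 of 3 WT libraries, the SPATS2L region at 115690 bp from the gene. In K243A they lay inside RASAL1 (chromosome 12, 113120164 to 113121014) and near COG1 and HDGFL1, strong in no WT library. For the other variants the lost regions were weaker in WT, with mean WT ranks of 26717 or more. They lay near or inside TEX44, FN1 and TMCO4 in A264C, MARCHF10, SNX16 and WDPCP in E260A, ADGRG1, EPOR and LAPTM5 in N278D, PHLDA1, LMNA and SLC2A10 in Q261A, RNFT2, IMPA1 and MC3R in Y253A, and LZTS2, GET3 and GRK2 in rep263A. Regions were named by the nearest gene end at any distance, which was 247670 bp for FN1, 194028 bp for PHLDA1 and 182540 bp for SNX16. The MARCHF10 and WDPCP regions were also called in 3 of 3 Empty libraries, the GRK2 region in 2, and the FADD, RASAL1, LMNA, IMPA1, MC3R, LZTS2 and GET3 regions in 1.

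The regions gained in rep217A lay near GNLY (chromosome 2, 85712887 to 85713674, mean rank 1274 in rep217A), near SLC52A3 (chromosome 20, 755478 to 756286) and inside BTG4 (chromosome 11, 111451840 to 111452591), each strong in both rep217A libraries. E260A gained a region inside EVC (chromosome 4, 5751009 to 5751483, mean rank 2619), strong in 3 of 3 E260A libraries, and regions inside ZBTB49 and near TOB1. The regions gained in N278D lay near or inside GNLY, KHDRBS3 and MBP, in Y253A UBL3, ST3GAL1 and MIPEP, in rep263A ADCY8, CBLN4 and GNLY, and in A264C EVC, TOB1 and, inside DIP2C, a site 165695 bp from LOC124905455. The Y253A region named by ST3GAL1 was 326369 bp from it. Q261A gained a region inside MAD1L1 and regions 985270 bp from PCDH7 and 275280 bp from INHBA, their nearest genes. G244E gained 2 regions inside ARID1B, which encodes a chromatin remodelling subunit, and 1 near TUNAR. K243A gained regions inside FTH1, the ferritin heavy chain gene, inside ARID1B and 106546 bp from EGFLAM. Each of these gained regions was also called in at least 1 library of another variant. The GNLY region was called in every library of A264C, E260A, N278D, Q261A, Y253A, rep217A and rep263A, and the EVC region in every library of A264C, E260A, Q261A, Y253A and rep263A. Empty libraries had a peak at the EVC region of E260A in 1 of 3 and at the EGFLAM region in 2 of 3. Of the regions that separated WT from Empty, A264C libraries had a peak at 89.4% ± 2.10, N278D at 86.6% ± 1.08, Y253A at 86.1% ± 1.26, E260A at 84.3% ± 0.362 and Q261A at 82.5% ± 1.95 (n = 3 each), and rep263A at 79.3% ± 2.73 (n = 2). K243A had 49.3% ± 7.24 and G244E 42.9% ± 7.14 (n = 3 each), and rep217A 50.001% ± 2.86 (n = 2), at each library's own depth and with no test.

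On average, libraries of the same group resembled each other more than libraries of different groups. The Jaccard index of the strongest peaks, the shared over the combined length, averaged 0.611 within and 0.434 between groups (permutation of group labels, p = 1e-05), and 26 of the 31 libraries were nearest to a library of their own group. WT libraries reached 0.742 with each other and 0.737 with A264C. N278D and Y253A reached 0.667 with each other against 0.559 and 0.570 with WT, and E260A and Y253A 0.639 against 0.536 for E260A with WT. Empty was an exception, with 0.136 between its own libraries and 0.185 with G244E, 0.171 with K243A, 0.161 with rep217A and 0.142 with rep263A.

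At the MITF gene itself, WT libraries had 37 to 42 peaks of −log10 q of at least 5, and Empty libraries 0 to 1. These counts are at own depth, where WT was at least 38.5 times as deep as Empty, so depth may give much of this contrast. The strongest 10000 peaks held 3 at MITF in each WT library and 3 to 6 in Empty. The rank of the strongest MITF peak was 1112 to 2065 in WT, 449 to 1572 in Empty, 57 to 67 in N278D and 276 to 361 in Y253A, ranks within each library's own list that show no change by themselves. Exons were not used here, so these peaks do not check the labels.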

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

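Both thinnings and the −log10 p of at least 8 were chosen only after the data had been seen. Over 160 results and 1617 values under other settings, 1346 counted as unchanged, 132 no longer passed or shrank, 115 newly passed or grew, and 24 turned. Tested values that counted as unchanged kept their side of the threshold. They include values that changed sign where neither setting passed. An example is the log2 peak number of G244E minus WT, at -0.307 to 0.516 with a replicate left out. For a count, a change means a factor of more than 1.5. The values that changed follow, as the variant minus WT unless marked otherwise, and the cause was not tested except where the construction of a setting gives it. No call on the recovery of WT regions changed with ranking by fold, the 5000 or 20000 strongest peaks, a −log10 q of at least 5 or overlaps of at least 50%. The E-box, motif and MITF exon results, with all their alternatives, were not run. The lists give no read totals, so depth rests on the recovered background, and depth and group cannot be varied separately in these libraries.

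A −log10 q of at least 5 moved the log2 difference in peak number to 6.84 (WT minus Empty), -1.92 (G244E), -1.53 (K243A) and -1.26 (rep217A). It moved regions of WT alone to 177 (A264C), 1348 (E260A), 25121 (G244E), 19524 (K243A), 359 (N278D), 1141 (Q261A), 742 (Y253A) and 3371 (rep263A), and regions of the other group alone to 0 (Empty), 5 (G244E), 1 (K243A), 780 (rep217A) and 1093 (rep263A). At their own depth, a −log10 p of at least 8 gave log2 differences in peak number of 5.60 (WT minus Empty), -1.84 (G244E), -1.48 (K243A) and -1.23 (rep217A).

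Thinned to the depth of the shallowest library other than Empty, with a −log10 p of at least 8, the log2 difference in peak number was 0.30 (E260A), 0.50 (N278D), 0.45 (Q261A), 0.40 (Y253A), -0.30 (rep217A) and 0.40 (rep263A). Regions of WT alone then numbered 101 (A264C), 262 (E260A), 1007 (G244E), 390 (K243A), 107 (N278D), 86 (Q261A), 156 (Y253A), 2188 (rep217A) and 188 (rep263A), and regions of the other group alone 330 (A264C), 1225 (E260A), 416 (K243A), 1554 (N278D), 1235 (Q261A), 1290 (Y253A), 1133 (rep217A) and 1837 (rep263A). Fewer peaks enter there by construction, which does not account for the count of K243A alone, which rose from 206. Among the strongest peaks at this depth, recovery differed by -2.28 (rep263A) percentage points. Survival genes differed by 1.47 (E260A). Lysosome genes differed by -3.53 (Q261A) and -2.27 (Y253A). DNA repair genes differed by -2.13 (Y253A) and -1.83 (rep217A). Lineage genes differed by 1.2 (K243A). Invasive-state genes differed by 2.3 (rep217A). Housekeeping genes differed by -1.4 (E260A), -1.8 (N278D) and -1.87 (Y253A).

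With all libraries thinned to the upper limit of the depth of Empty and a −log10 p of at least 8, the log2 difference in peak number was 1.16 (WT minus Empty) and 0.57 (Q261A), and against Empty 547 regions belonged to WT alone and 42 to Empty alone. Recovery among the strongest peaks then differed by -3.02 (K243A), -3.03 (Q261A) and -1.53 (rep263A) percentage points, and gene-end share by -6.15 (rep217A). Survival genes differed by 3.27 (WT minus Empty). Lysosome genes differed by -1.53 (K243A), -3.07 (rep217A) and -2.57 (rep263A). DNA repair genes differed by -1.67 (N278D) and -2.37 (rep217A). Lineage genes differed by -2.6 (WT minus Empty) and 0.6 (rep217A). Housekeeping genes differed by -3.47 (E260A), -2.73 (N278D), -2.2 (Q261A) and -2.8 (Y253A). Keratinocyte genes differed by 0.467 (E260A).

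Ranked by fold enrichment, gene-end share differed by -11.5 (WT minus Empty), 5.77 (rep217A) and -2.31 (rep263A) percentage points. Pigmentation genes came to -0.667 (WT minus Empty), 0 (G244E) and 3.33 (K243A). Survival genes came to -3.33 (WT minus Empty), 2.67 (G244E) and 2.67 (K243A). Lysosome genes came to 1.33 (WT minus Empty), -2.67 (E260A), 3.67 (G244E), 5.33 (K243A), 5 (rep217A) and -0.5 (rep263A). DNA repair genes came to -2 (E260A) and -2.33 (N278D). Lineage genes came to 1.17 (rep217A). Invasive-state genes came to -3.33 (WT minus Empty), 2 (G244E) and 2 (K243A). Housekeeping genes came to -7.67 (WT minus Empty), 6 (G244E) and 6 (K243A). Keratinocyte genes came to 0.333 (E260A).

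With the 5000 strongest peaks, gene-end share differed by -3.57 (WT minus Empty) percentage points. Pigmentation genes differed by 2.67 (E260A) and 2.67 (N278D). Survival genes differed by 1.67 (WT minus Empty) and -1.67 (G244E). Lysosome genes differed by -6 (Q261A), -6.67 (Y253A) and -3.33 (rep217A). DNA repair genes differed by -2.33 (Q261A), -2.67 (Y253A) and -2.17 (rep217A). Lineage genes differed by 2 (rep217A). Invasive-state genes differed by -2.33 (WT minus Empty). Housekeeping genes differed by -2.33 (E260A), -2.33 (Q261A) and -3 (Y253A). Keratinocyte genes differed by 0 (E260A), -1 (N278D), -1 (Q261A), -1 (Y253A) and -1 (rep263A).

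The 20000 strongest peaks gave other values for gene lists only. Pigmentation genes stood at -1.67 (G244E). Lysosome genes stood at 0 (E260A), -2.33 (G244E), -2 (K243A), -1 (N278D), -1.5 (rep217A) and 0 (rep263A). DNA repair genes stood at 3.33 (WT minus Empty), -1.67 (E260A) and -1.67 (N278D). Lineage genes stood at -2 (WT minus Empty), 2.67 (G244E) and 2.67 (K243A). Keratinocyte genes stood at 1 (E260A).

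Counted over the gene body with 10000 bp to each side, gene lists changed as follows. Pigmentation genes reached -2.67 (G244E). Survival genes reached 3.67 (WT minus Empty). Lysosome genes reached -2 (E260A), -2.33 (N278D), -1.67 (rep217A) and -2.17 (rep263A). DNA repair genes reached -2.67 (E260A) and -3 (N278D). Lineage genes reached 2 (rep217A). Lymphoid genes reached -3 (WT minus Empty). Only the strongest summit of each interval gave gene-end shares that differed by 3.42 (WT minus Empty), -4.11 (E260A) and -5.18 (rep263A) percentage points.

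With the 10000 strongest peaks of each library, regions of WT alone numbered 2521 (Empty), 53 (A264C), 754 (E260A), 1435 (G244E), 735 (K243A), 674 (N278D), 372 (Q261A), 693 (Y253A), 1986 (rep217A) and 474 (rep263A), and regions of the other group alone 137 (A264C), 1070 (E260A), 323 (K243A), 952 (N278D), 552 (Q261A), 1022 (Y253A), 1769 (rep217A) and 666 (rep263A). Fewer peaks enter here too by construction, but the count of K243A alone rose from 206. An overlap of at least 50% of the region left 56 (Empty), 257 (G244E) and 110 (K243A) regions of the other group alone.

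Leaving out a replicate of every group in turn gave these ranges. Recovery over all peaks differed by -9.17 to -8.33 (rep263A) and among the strongest peaks by -9.93 to -9.15 (Q261A) and -8.78 to -7.24 (rep263A) percentage points. Gene-end share differed by 3.35 to 9.37 (WT minus Empty), -7.29 to -4.51 (E260A), 9.39 to 11.97 (G244E), 6.55 to 8.8 (K243A), -9.87 to -6.19 (Q261A) and -7.99 to -6.22 (rep263A). Survival genes ranged over 0 to 2 (WT minus Empty) and 2 (E260A). Lysosome genes ranged over -3.5 to -1.5 (E260A), -4.5 to -4 (G244E), -3 to -2.5 (K243A), -3 to -2 (N278D), -4 to -2.5 (rep217A) and -4 to -3.5 (rep263A). DNA repair genes ranged over -3 to -2.5 (E260A), -3 to -2.5 (N278D), -2.5 to -1.5 (Y253A) and -2.5 to -2 (rep217A). Lineage genes ranged over 3 (rep217A). Housekeeping genes ranged over -3 to -2 (Y253A). Keratinocyte genes ranged over 1.5 to 2 (E260A). Leaving out a library lowers the number that must share a region, so these counts rise by construction. Regions of WT alone ranged from 57130 to 61847 (Empty), 5647 to 9151 (A264C), 9748 to 12944 (E260A), 29042 to 33070 (G244E), 26182 to 28533 (K243A), 8551 to 12184 (N278D), 10965 to 14350 (Q261A), 9746 to 12401 (Y253A), 27731 to 40957 (rep217A) and 13939 to 20727 (rep263A). Regions of the other group alone ranged from 2005 to 3068 (Empty), 5932 to 8977 (A264C), 17549 to 19460 (E260A), 2778 to 14188 (G244E), 1395 to 3653 (K243A), 14087 to 17132 (N278D), 6823 to 8914 (Q261A), 14717 to 16279 (Y253A), 10242 to 125202 (rep217A) and 5267 to 75936 (rep263A), and the highest values of rep217A and rep263A rest on 1 library.

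Replicate numbers did not pair the libraries. Over 146 pairs of libraries with the same number in different groups, the correlation of their deviations from the group means was -0.0171 to 0.0342, and 13 of 31 libraries correlated best with their own number. With the replicate block, 3 of 140 results changed, namely the lysosome genes of E260A, K243A and N278D, at -2.67 each with a permutation p of 0.0556. With identical files counted as separate libraries, 2 of 140 changed, the lysosome genes of Q261A and the housekeeping genes of Y253A, which newly passed at -2.33 each.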

Other observations

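The tests of depth, of untargeted signal and of other splits in this part were set out after the results they bear on had been seen. Within the lysosome list, CTSA was strong in all WT libraries and in none of 5 variants, and other genes were absent from the strongest peaks of fewer variants. GLA, which encodes alpha-galactosidase A, and FLCN, which encodes folliculin, were strong in 3 of 3 WT libraries and in 0 of 2 rep217A libraries, and in every library of the other variants. HEXA, which encodes a hexosaminidase subunit, was strong in 0 of 3 libraries of G244E and of K243A and in 3 of 3 of WT, A264C, N278D, Q261A and Y253A. LAMP1, which encodes a lysosomal membrane protein, was strong in 0 of 3 libraries of E260A and of Y253A and in 0 of 2 of rep217A. MCOLN1, which encodes a lysosomal cation channel, was strong in 0 of 2 libraries of rep263A. SQSTM1, which encodes an autophagy receptor, went the other way, with 0 of 3 in WT and 3 of 3 in K243A. These genes were picked for their values, and no test of single genes was run. Among 10000 random lists of the same size, WT counts stood at the percentile 87.48 for DNA repair genes, 58.64 for survival genes, 8.63 for invasive-state genes and 0.65 for lineage genes. The random lists held only genes with a strong peak in any library, which can lower these percentiles.

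Fewer strong peaks than in WT were called in K243A, G244E and rep217A. At the common depth the log2 difference from WT was 0.16 in K243A and 0.15 in G244E, so a difference in depth may account for their lower numbers. For rep217A the difference at the common depth was -0.30 (n = 2, permutation p = 0.00839), which argues against depth as the whole cause. At the depth limit of Empty it was -0.28 and did not pass (permutation p = 0.745), in a test that also held the Empty libraries. Neither the amount of HA-tagged protein in each group nor its effect was tested, and an effect of the variant stays open as untested in all 3 groups.

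WT regions were missing among the strongest peaks of 8 variants, and at the common depth 7 of them (E260A, G244E, K243A, N278D, Q261A, Y253A and rep217A) still found fewer than WT. In E260A, N278D, Q261A and Y253A this argues against depth as the whole cause. Thinned peaks kept the widths called at each library's own depth. Over all peaks the median width averaged 329 bp in WT, 202 in G244E, 240 in K243A and 207.5 in rep217A. Wide peaks overlap more easily, so thinning cannot decide on depth as the whole cause in G244E, K243A and rep217A. Depth stays open there, for rep263A (-2.28 percentage points, not passing), and as part of the cause in Q261A. Differences shrank in all 7 between own and common depth. They went from -18.1 to -7.67 points in K243A, -9.41 to -4.68 in Q261A and -28.1 to -16.1 in G244E. The others went from -12.7 to -8.19 in N278D, -31.1 to -21.3 in rep217A, -12.8 to -9.09 in Y253A and -14.3 to -10.8 in E260A. At the depth limit of Empty neither K243A (-3.02) nor Q261A (-3.03) passed. Thinning also lowered WT recovery, from 94.4% to 81.8%, so the shrinkage alone cannot show a part played by depth. Background pileup averaged 1.06 in Y253A, 0.997 in N278D and 0.895 in E260A, against 1.15 in WT. At 0.457, rep263A found 86.6% of WT regions at its own depth (n = 2). Y253A found 81.6%, N278D 81.7% and E260A 80.1%. These values argue against depth as a large part of the cause in Y253A, N278D and E260A. Q261A, at 0.774, found 85.0% ± 2.21, within its spread of rep263A. Untargeted signal, as in Empty, in place of HA-MITF signal would raise the share of the 2404 to 3107 Empty regions called. In E260A, N278D, Q261A and Y253A that share averaged -6.47 percentage points from WT at the common depth. WT itself called 66.2% of these regions, so a variant that lost WT regions can score lower whatever its untargeted signal. The share therefore cannot decide on this explanation in these variants. In G244E and K243A it averaged 8.90 points above WT (permutation p = 1e-05 each), so untargeted signal is a candidate explanation there, and in rep217A it was 2.44 points above (permutation p = 0.263), which leaves it open. That test was set for these 3 variants together, where rep217A would have left it open, and divided after the values were seen, and a change in the sites occupied stays an untested hypothesis for E260A, N278D, Q261A and Y253A.

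The share of strongest peaks near gene ends moved in opposite directions between variants. At the common depth, 5 variants (E260A, N278D, Q261A, Y253A and rep263A) still lay below WT and 2 (G244E and K243A) above it, which argues against a difference in depth between the libraries as the cause of either shift. Untargeted signal was not tested for this share, because the Empty share changed sides with the ranking (WT minus Empty -11.5 points by fold). A preference of the variants for promoters or for distal sites is a biological candidate explanation that was not tested.

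For each comparison of 3 libraries with 3, only 1 of the 10 splits of the 6 libraries, the real one, gave as many group-specific regions, and 10 splits are too few for a share under 0.05. These counts are at each library's own depth, and a difference in depth between groups can by itself raise the real count. The real and the highest other counts were 39890 and 1248 for WT against Empty, 15909 and 2458 for G244E, 13886 and 1956 for E260A, 12633 and 2993 for K243A, 11948 and 1790 for Y253A, 11210 and 1706 for N278D, 7342 and 2061 for Q261A, and 3291 and 2567 for A264C. In rep217A and rep263A, with 5 libraries each, they were 26808 and 10698, and 9924 and 9290.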
